A study of Mus musculus with 9 samples.

How the data were processed

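RNA was isolated from sorted cells as total RNA with DNase treatment, ribosomal RNA was depleted and libraries were made with NEBNext kits, per the labels' protocols. The authors used bcl2fastq 2.19.1, STAR 2.5.3a and the mouse genome build mm10, per the submitters' processing notes, which do not give the role of each tool. The deposited values are whole-number read counts per Ensembl gene with 1 column per library and no scaling, per the file headers and the values themselves. Annotation, strand and counting settings are not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. The table had 52636 Ensembl gene IDs in 15 columns of libraries. The 9 columns that matched the samples by name were used, and the other 6 were not used here.

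Gene symbols and positions came from the GENCODE M21 annotation (mm10, also called GRCm38). A symbol was found for 52403 IDs and none for 233, and 52489 IDs were in the annotation. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by the default low-count rule of edgeR over the 3 groups, which left 16198. Libraries were scaled with trimmed mean of M values factors. A quasi-likelihood model was fitted to all 9 libraries with line as the only term, the 3 comparisons between lines were tested, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Every adjusted p of a gene is from this test unless another is named. CPM values in the text are counts scaled to the library total and these factors with no pseudocount, with the mean and SD of 3 libraries. Standard errors of log2 fold changes were worked back from the test, as the absolute change divided by the square root of its F statistic. Log2 CPM for list tests and principal components used a prior count of 2.

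Before the data were examined, 27 gene lists with 355 entries were written down from general knowledge, and all 355 were matched to IDs. Each list with at least 5 tested members was compared with all other genes by the camera test of limma with a preset correlation of 0.01, and adjusted over the 27 lists of a comparison. Camera was also run with the correlation estimated per list, and fry was run beside it. Ranges of a list's adjusted p cover the camera alternatives only, since fry tests against no change rather than against other genes. The genes named in the text were picked by a rule also set beforehand. It took the altered and sorted genes, and the 6 genes per direction with the largest called changes, a mean of at least 5 CPM in the higher group and no overlap between replicates, predicted genes left out. It added from each list the 2 members with the smallest adjusted p, and up to 4 for naive, general, formative and primitive endoderm lists, 133 genes in all. Where a group had few or no counts, a ratio with a 95% exact interval of counts, or a lower limit from 3 counts, was given. The members of each list were counted again without Nanog-null replicate 2, an alternative added after the data were seen.

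The alternatives written before the data were examined were factors from the median of ratios, library totals alone, DESeq2, no low-count filter, a filter of at least 5 CPM in 3 libraries, a fit of only the 2 groups compared, the replicate number as a block, a test against a fold change of 1.5, and each library left out in turn. Ranges of a gene's adjusted p cover all of these alternatives. They include the fit with no low-count filter, whose very small values carry little weight. They also include the test against a fold change of 1.5, which asks for a larger change. The overlap of calls was compared with 20 simulations of unchanged groups that share the same libraries. With 3 libraries against 3, an exact permutation test of 1 gene cannot go below 0.1.

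The procedure was tested on simulated data drawn from the means and library sizes of these samples. Only 66 or 67 genes per fold size were changed in each simulation. The real comparisons called far larger shares of genes (48.5%, 13.2% and 54.4%). Recovery and false shares depend on how many genes change, so those given here hold for the simulated setting and may differ in the real comparisons. For the Esrrb line against the Nanog-null line (15928 genes), 92.4% of 4-fold, 73.1% of 2-fold and 55.2% of 1.5-fold changes were recovered, and 3.3% of calls were false. For the Esrrb+Nanog line against the Esrrb line (15912 genes) the shares were 95.5%, 70.1% and 47.8%, with 7.8% false. For the Esrrb+Nanog line against the Nanog-null line (15910 genes) they were 95.5%, 70.1% and 43.3%, with 6.7% false.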

Results

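RNA from 9 samples of mouse embryonic stem cells was sequenced, 3 libraries from each of 3 lines. The Nanog-null line (titled NanogKO, 44C6) is the reference. The Esrrb line (NanogKO:Esrrb, 44J) and the Esrrb+Nanog line (NanogKO:Esrrb:Nanog, 44JN) are named in the sample titles for these added genes, and the labels give both the same genotype. All cells were grown in serum with leukaemia inhibitory factor (LIF) and sorted for PECAM on the surface and for absence of PDGFRA, a receptor of primitive endoderm. Library totals ran from 21808120 to 32496267 counts. They were 21808120, 25695618 and 29823354 in the Nanog-null line, 29606263, 32496267 and 26726952 in the Esrrb line, and 25948627, 24398291 and 28583717 in the Esrrb+Nanog line. The first principal component held 71.4% of the variance between libraries and set the Nanog-null line apart from the others. The second held 11.7% and separated the Esrrb line from the Esrrb+Nanog line. Each group is a single line, so the added gene and the line cannot be separated in any comparison. Adjusted p-values measure the spread between these libraries, since the labels do not say whether replicates were separate cultures.

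The altered genes followed the titles in every library. Nanog (ENSMUSG00000012396, mm10 chromosome 6, 122707489 to 122714633, GENCODE M21), a homeodomain regulator of pluripotency, was at normalised read counts (CPM, scaled to library size) of 14.3, 14.3 and 16.02 in the Nanog-null libraries. It was at 29.7, 35.1 and 30.4 CPM in the Esrrb libraries and at 221, 289.5 and 333 CPM in the Esrrb+Nanog libraries. The labels do not say which part of Nanog was removed, so the remaining reads neither test nor contradict the deletion. Esrrb (ENSMUSG00000021255, chromosome 12, 86361117 to 86521628), an orphan nuclear receptor of naive cells, was at 273, 253 and 303 CPM in the Nanog-null libraries. Its level was 769, 949 and 692 CPM in the Esrrb libraries and 1113, 1151 and 1056 CPM in the Esrrb+Nanog libraries. The sorting marker Pecam1 fell from 101 ± 8.6 CPM (SD, n = 3) in the Nanog-null line to 61.9 ± 8.7 in the Esrrb line (log2 change -0.71, adjusted p = 0.000176), and lay at 49.8 ± 4.0 in the Esrrb+Nanog line.

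**Figure D1:**
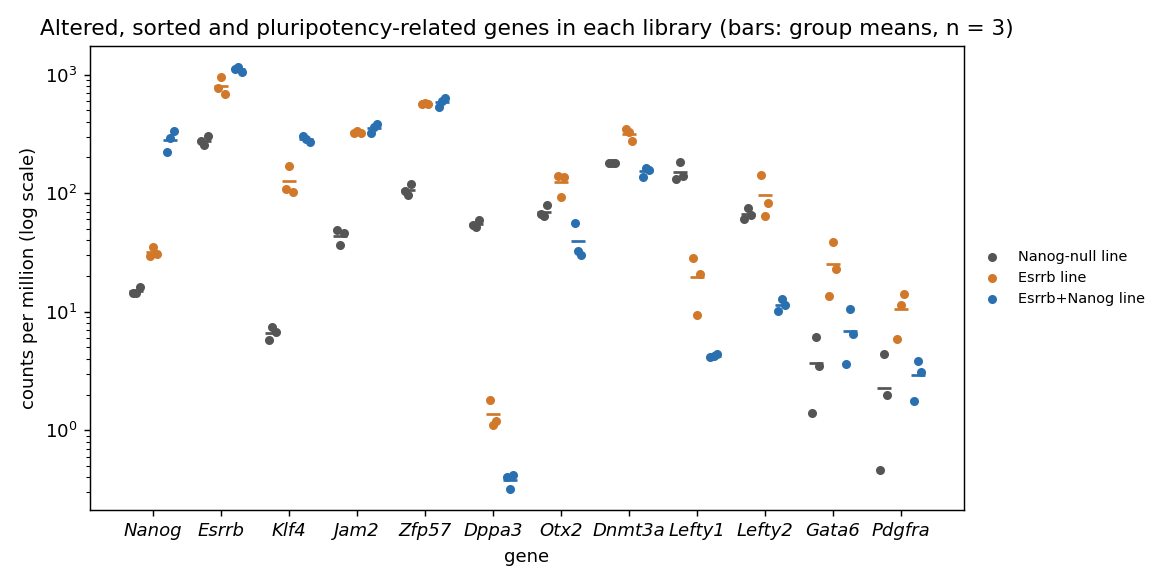
Normalised read counts (CPM, y axis, log scale) for 12 genes in each of the 9 libraries, coloured by line; bars are means of 3 libraries. Nanog was between 221 and 333 CPM in the Esrrb+Nanog line and at most 35.1 CPM in every other library.

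The comparison of the Esrrb line with the Nanog-null line asks what differs where cells without Nanog carry added Esrrb. Of 15 genes of naive pluripotency, the state of the early epiblast, 11 were higher in the Esrrb line, and Klf4, a Krüppel-like reprogramming factor, rose most among them. Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466) went from 6.65 ± 0.82 to 127 ± 38 CPM (SD, n = 3 per line), a log2 change of 4.25 ± 0.19 (SE, adjusted p = 3.42e-08). The adhesion gene Jam2 rose from 43.9 ± 6.4 to 326 ± 8.4 CPM, Zfp57, a guardian of imprints, from 107 ± 12 to 568 ± 2.7 CPM, and Nr0b1, a nuclear receptor of naive cells, from 66.7 ± 4.6 to 239 ± 22 CPM. Dppa3, a maternal factor also known as Stella, went the other way, from 55.3 ± 4.1 to 1.36 ± 0.38 CPM (log2 change -5.34 ± 0.15, adjusted p = 1.81e-09). Esrrb itself rose by 1.54 ± 0.11 on the log2 scale (SE, adjusted p = 7.37e-07) and Nanog by 1.09 ± 0.14 (adjusted p = 5.92e-05).

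Of the 15 naive genes, 11 were higher, 1 was lower and 3 were not called, and the counts adjusted over the list alone were also 11 and 1. The list stood above other genes in limma's camera test with its preset correlation (adjusted p = 0.000245). With an estimated correlation its adjusted p was 0.279, the highest of its alternatives, which began at 8.49e-07. Among general pluripotency genes, shared by naive and later states, 8 of 15 were higher and 1 was lower, the same counts as adjusted over the list alone. The epidermal growth factor-like co-receptor Tdgf1 rose from 278 ± 29 to 632 ± 41 CPM, the RNA-binding factor L1td1 from 915 ± 36 to 1868 ± 55 CPM, and Foxd3 from 49.2 ± 1.3 to 102 ± 4.9 CPM. As a list, general pluripotency genes narrowly missed the threshold (adjusted p = 0.0508, range 0.0111 to 0.627 over its alternatives). The list passed without Nanog-null replicate 1 (0.0483) or 3 (0.0405), Esrrb replicate 1 (0.0495) or 2 (0.026), or Esrrb+Nanog replicate 1 (0.0408) or 3 (0.049).

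Genes of the formative and primed epiblast, which prepare for lineage choice, were lower in the Esrrb line in 10 of 14 cases and higher in 2, with the same counts adjusted over the list alone. The neural and epiblast factor Pou3f1 fell from 64.2 ± 9.5 to 12.7 ± 2.9 CPM, the Wnt antagonist Sfrp2 from 56.0 ± 6.7 to 23.6 ± 0.33 CPM, and Tead2 from 140.1 ± 15 to 73.6 ± 4.1 CPM. The DNA methyltransferase Dnmt3a rose instead, from 181 ± 0.28 to 315 ± 36 CPM. The list test gave an adjusted p of 0.0219, and 0.627 with an estimated correlation, the highest of a range that began at 0.0017. Without Nanog-null replicate 2, 9 members were lower.

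Imprinted genes, expressed from 1 parental copy, were lower in 14 of 16 cases and higher in none, in both the count over all genes and that adjusted over the list alone. The maternally expressed RNAs Meg3 (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726) and Rian (ENSMUSG00000097451, 109603940 to 109661716) lie side by side. Meg3 fell from 301 ± 9.4 to 13.9 ± 2.3 CPM (log2 change -4.43 ± 0.15, adjusted p = 4.21e-09) and Rian from 417 ± 47 to 20.1 ± 1.5 CPM (log2 change -4.37 ± 0.15, adjusted p = 3.15e-09). The list had an adjusted p of 1.78e-06, and 0.0984 with an estimated correlation, the highest of a range that began at 2.32e-10. Genes of the 2-cell-like state, a rare state that resembles the early embryo, were all higher, 11 of 11 tested and 11 adjusted over the list alone. Zscan4a rose from 0.328 ± 0.093 to 12.7 ± 4.3 CPM and Zscan4d from 0.312 ± 0.072 to 11.4 ± 4.0 CPM, with log2 changes of 5.28 ± 0.45 and 5.18 ± 0.50. The adjusted p was 5.53e-07 for this list, and 0.554 with an estimated correlation, the highest of a range that began at 1.54e-11. The Zscan4 genes and the Usp17l genes of this list are near-identical copies, so how reads divide between their members is uncertain.

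Targets of the tumour suppressor p53 were higher in 10 of 13 cases, none was lower, and the counts adjusted over the list alone were the same. Ccng1, a cyclin induced by p53, rose from 119 ± 18 to 303 ± 45 CPM and Phlda3, an inhibitor of AKT, from 30.5 ± 2.1 to 57.3 ± 6.5 CPM. The list's adjusted p was 0.0012, and 0.523 with an estimated correlation, the highest of a range that began at 2.73e-05. Nuclear genes of oxidative phosphorylation were higher in 11 of 15 cases (12 adjusted over the list alone, 8 without Nanog-null replicate 2), by small amounts. The complex I subunit Ndufa9 rose from 76.8 ± 2.3 to 134 ± 4.8 CPM and the cytochrome oxidase subunit Cox5a from 104 ± 2.2 to 168 ± 5.9 CPM. The list's adjusted p was 0.00286, and 0.627 with an estimated correlation, the highest of a range that began at 0.00104. None of the 7 tested mitochondrially encoded genes was called by edgeR or when adjusted over the list alone (list adjusted p = 0.945).

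Keratins and other trophoblast genes, markers of the placental lineage, were lower in 8 of 14 cases and higher in none, with the same counts adjusted over the list alone. Krt18 was at 57.0 ± 40 CPM in the Nanog-null line and 7.28 ± 0.92 in the Esrrb line, and Krt7 at 3.91 ± 1.7 and 0.117 ± 0.032 CPM. Nanog-null replicate 2 stood apart in these genes, with a median log2 ratio of 0.427 to the other 2 Nanog-null libraries, and Krt18 was at 102 CPM in it against 24.4 and 44.4. Without that replicate the log2 change of Krt18 was -2.26 in place of -2.97, and 5 members were lower. The list was called at an adjusted p of 0.0336, and 0.627 with an estimated correlation, the highest of a range that began at 0.0017. The call ended without Nanog-null replicate 2 (0.0519) or 3 (0.0635), and with a minimum of 5 CPM in 3 libraries (0.232).

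Primitive endoderm genes, of the lineage that lines the blastocyst cavity, split in the Esrrb line, with 5 of 17 higher, 4 lower, 8 not called and the same counts adjusted over the list alone. The laminin gene Lama1 rose from 43.6 ± 19 to 136 ± 41 CPM. Lrp2, an endocytic receptor, fell from 329 ± 78 to 84.7 ± 4.0 CPM and Lamb1, a laminin chain gene, from 166 ± 33 to 65.2 ± 9.3 CPM. The sorted-out marker Pdgfra rose from 2.29 ± 2.0 to 10.4 ± 4.2 CPM (log2 change 2.16 ± 0.52, adjusted p = 0.00474, and log2 change 2.99 without Nanog-null replicate 2). That library stood apart most in primitive endoderm genes, with a median log2 ratio of 1.24 to the other Nanog-null libraries and 10 of 17 members over 2-fold higher. Without it, 8 members were higher and 4 lower. The list was not called (adjusted p = 0.787).

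Fibroblast genes, which would mark feeder or other stromal cells, were lower in 5 of 8 cases and higher in 1 (4 and 1 without Nanog-null replicate 2), and the counts adjusted over the list alone were 5 and 1. Acta2, smooth muscle actin, was at 7.69, 54.3 and 16.1 CPM in the Nanog-null libraries and had 3 counts in all Esrrb libraries together, a ratio of 768 (95% counting interval 262 to 3730). Its fitted log2 change was -9.38, -8.27 without Nanog-null replicate 2 and -12.44 without Esrrb replicate 2. The median log2 ratio of Nanog-null replicate 2 to the other Nanog-null libraries was 0.911 over this list, with 4 of 8 members over 2-fold higher, against 0.001 over all tested genes. The list itself was not called (adjusted p = 0.256).

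Signalling lists held members that moved both ways and none was called. Among targets of LIF and STAT3, 5 of 12 were higher and 3 lower (6 and 3 adjusted over the list alone, adjusted p = 0.256), with the kinase gene Pim1 falling from 258 ± 29 to 100.2 ± 2.2 CPM. Without Nanog-null replicate 2, 2 were lower. Targets of FGF and ERK gave 9 higher and 5 lower of 16 (9 and 5 adjusted over the list alone, adjusted p = 0.368), with Etv4 up from 51.2 ± 4.3 to 229 ± 48 CPM and the feedback inhibitor Spry1 down from 52.2 ± 2.4 to 20.7 ± 1.3 CPM. Of 11 Wnt targets, 5 were higher and 3 lower (5 and 4 adjusted over the list alone, 2 lower without Nanog-null replicate 2, adjusted p = 0.402), and the feedback gene Axin2 rose from 9.75 ± 0.25 to 31.3 ± 3.6 CPM. Nodal targets gave 3 higher and 3 lower of 8 (4 and 3 adjusted over the list alone, adjusted p = 0.945), with the Nodal antagonist Lefty1 down from 151 ± 29 to 19.5 ± 9.5 CPM. BMP targets gave 3 higher and 2 lower of 9, also adjusted over the list alone (adjusted p = 0.616), with Id1 up from 31.0 ± 1.6 to 87.5 ± 7.3 CPM. Retinoic acid targets gave 1 higher and 6 lower of 8, also adjusted over the list alone (adjusted p = 0.141), with the meiotic entry gene Stra8 down from 17.6 ± 5.0 to 1.19 ± 0.52 CPM. Nanog-null replicate 2 had a median log2 ratio of 0.334 to its partners in this list, and 3 members were lower without it.

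Of the remaining lists, 7 of 16 glycolysis genes were higher and none lower, 5 without Nanog-null replicate 2 (7 adjusted over the list alone), including the glucose transporter Slc2a1 at 488 ± 81 and 1048 ± 82 CPM. That list had an adjusted p of 0.0567 (range 0.0148 to 0.636 over its alternatives) and passed without Esrrb replicate 2 (0.0471), Esrrb replicate 3 (0.017) or Esrrb+Nanog replicate 3 (0.049). Germline genes gave 6 higher and 2 lower of 12 (adjusted p = 0.245), with the RNA-binding gene Dazl at 5.28 ± 0.24 and 13.5 ± 2.2 CPM. DNA methylation genes gave 4 higher and 2 lower of 8 (adjusted p = 0.425), and cell-cycle genes 4 higher and 2 lower of 16 (adjusted p = 0.547). Parietal endoderm gave 3 higher and 2 lower of 10 (adjusted p = 0.746), visceral endoderm 1 and 1 of 6 (0.698), and primitive streak and mesoderm 1 and 1 of 7 (0.754). Basement membrane genes gave 5 higher and 7 lower of 15 (adjusted p = 0.616), and immediate-early and stress genes 4 and 4 of 12 (0.698). In all 8 of these lists the counts adjusted over the list alone were the same. Neuroectoderm genes gave 0 higher and 4 lower of 7 (1 and 4 adjusted over the list alone, 3 lower without Nanog-null replicate 2, adjusted p = 0.291). Replicate 2 had median log2 ratios of 0.436 in parietal endoderm, 0.275 in basement membrane and 0.339 in immediate-early genes. The list median, mean and test differed in sign for parietal endoderm, primitive streak, Nodal, BMP and mitochondrially encoded genes.

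Across all genes, 7849 of 16198 tested (48.5%) were called, 3924 higher and 3925 lower, and 1151 and 1435 of these by more than 2-fold. The named genes with the largest falls were Y-linked. Eif2s3y, a translation factor gene, had 0 counts in the Esrrb line and was at least 2640-fold lower. Uty, the Y-linked copy of Kdm6a, also had none and was at least 1240-fold lower. Ddx3y, an RNA helicase gene, had 1 count, a ratio of 6480 (95% counting interval 1160 to 256000). Its fitted log2 change was -12.18, and -13.98 without Esrrb replicate 1. These intervals and limits cover counting error only. The brain-enriched ubiquitin ligase gene Trim67 fell from 10.4 ± 4.3 to 0.138 ± 0.091 CPM (log2 change -6.19, and -6.84 without Esrrb replicate 1). Besides the Zscan4 genes, the largest rises were in Rapgef3, a cAMP-activated exchange factor gene, from 0.543 ± 0.24 to 19.8 ± 11 CPM, and in Wnt6, a Wnt ligand gene, from 0.431 ± 0.21 to 12.4 ± 1.9 CPM.

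**Figure D2:**
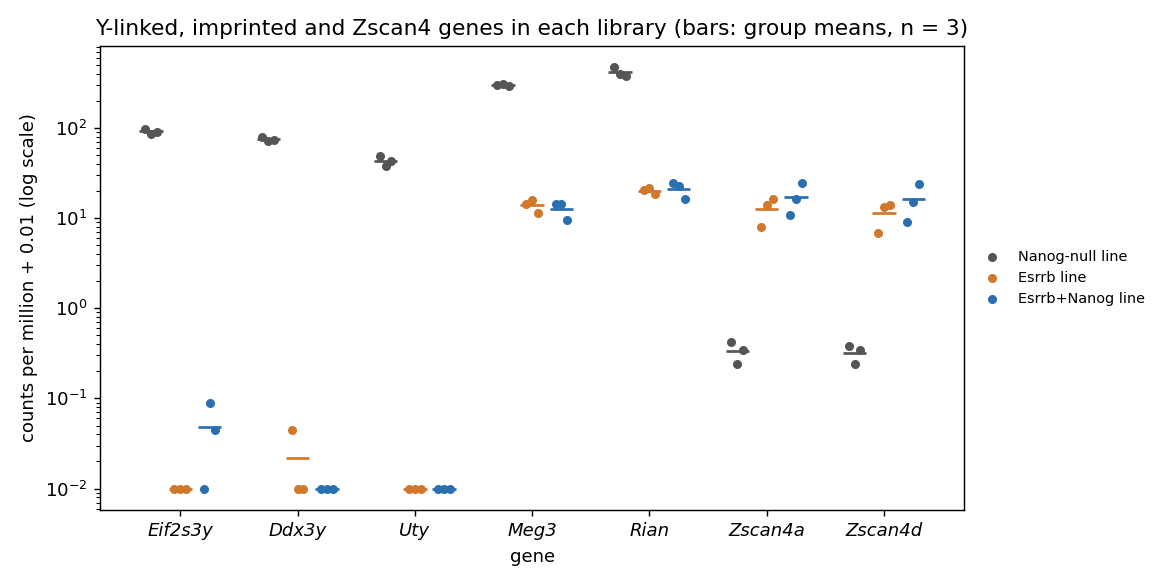
Normalised read counts (CPM plus 0.01, y axis, log scale) for Y-linked, imprinted and Zscan4 genes in each of the 9 libraries, coloured by line; bars are means of 3 libraries. Points at 0.01 are libraries with 0 counts, which include all 6 libraries of the Esrrb and Esrrb+Nanog lines for Uty.

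The comparison of the Esrrb+Nanog line with the Esrrb line asks what differs where Nanog is present as well. Nanog rose from 31.7 ± 2.9 to 281 ± 56 CPM (SD, n = 3 per line), a log2 change of 3.15 ± 0.13 (SE, adjusted p = 2.79e-07). Otx2, a homeobox factor of the epiblast leaving the naive state, fell from 123 ± 27 to 39.4 ± 14 CPM (log2 change -1.65 ± 0.22, adjusted p = 0.000642). The DNA methyltransferase Dnmt3a fell from 315 ± 36 to 153 ± 15 CPM and Dnmt3b from 462 ± 39 to 285 ± 10 CPM. The Nodal antagonist Lefty2 (ENSMUSG00000066652, chromosome 1, 180893108 to 180899103) fell from 96.3 ± 41 to 11.5 ± 1.3 CPM (log2 change -3.07 ± 0.25, adjusted p = 2.66e-05). Duox1, an oxidase gene (ENSMUSG00000033268, chromosome 2, 122315672 to 122347972), rose from 3.28 ± 0.32 to 47.5 ± 2.4 CPM (log2 change 3.86 ± 0.10, adjusted p = 2.07e-09).

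Naive genes moved both ways, with 3 of 15 higher, 4 lower, 8 not called and the same counts adjusted over the list alone. Klf4 rose again, from 127 ± 38 to 288 ± 17 CPM (log2 change 1.18 ± 0.16, adjusted p = 0.000708), as did the germ cell factor Prdm14, from 7.25 ± 0.088 to 13.7 ± 1.8 CPM. Dppa5a fell from 801 ± 67 to 534 ± 10 CPM, and Dppa3 from 1.36 ± 0.38 to 0.383 ± 0.053 CPM. The naive list was not called (adjusted p = 0.725). Of the general pluripotency genes, 6 of 15 were lower (8 adjusted over the list alone, 5 without Nanog-null replicate 2) and none was higher. The let-7 regulator Lin28a fell from 432 ± 21 to 273 ± 40 CPM and the threonine dehydrogenase gene Tdh from 372 ± 9.2 to 289.4 ± 8.1 CPM. Their adjusted p was 0.00418, and 0.602 with an estimated correlation, the highest of a range that began at 0.000813.

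Of the glycolysis genes, 10 of 16 were lower (11 adjusted over the list alone) and none was higher. The ATP-producing kinase gene Pgk1 went from 447 ± 27 to 284 ± 16 CPM and the isomerase gene Tpi1 from 481 ± 48 to 330.5 ± 26 CPM. The list's adjusted p was 4.2e-05, and 0.602 with an estimated correlation, the highest of a range that began at 3.51e-07. Targets of p53 were lower in 5 of 13 cases, also adjusted over the list alone, with Ei24 down from 181 ± 11 to 119 ± 9.8 CPM and the stress sensor Sesn2 from 247 ± 36 to 164 ± 16 CPM. The p53 list had an adjusted p of 0.0105, and 0.602 with an estimated correlation, the highest of a range that began at 0.00198. Cell-cycle genes were called lower as a list (adjusted p = 0.0113, and 0.613 with an estimated correlation, the highest of a range that began at 0.00176), but only the replication helicase gene Mcm3 of its 16 members was called, also adjusted over the list alone. Mcm3 went from 601 ± 18 to 511 ± 7.3 CPM, and its call ended without Esrrb replicate 1 (0.0586) or Esrrb+Nanog replicate 2 (0.053), in a range of 4.32e-05 to 1. The list call ended without Esrrb+Nanog replicate 1 (0.158).

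Neuroectoderm genes were called higher as a list (adjusted p = 0.0353), with 2 of 7 members higher, also adjusted over the list alone, and 3 higher without Nanog-null replicate 2. The neuroectoderm list had an adjusted p of 0.602 with an estimated correlation, the highest of a range that began at 0.00823. The eye and brain factor Pax6 rose from 4.19 ± 1.0 to 6.90 ± 0.72 CPM and the neural factor Sox1 from 5.47 ± 0.50 to 8.99 ± 2.1 CPM. The list call ended with library totals alone as the scale (0.0546), with no low-count filter (0.102), and without Esrrb replicate 1 (0.0578) or Esrrb+Nanog replicate 1 (0.0566) or 3 (0.0602). The call of Pax6 ended without Esrrb replicate 1 (0.0767) or Esrrb+Nanog replicate 3 (0.0562), in a range of 0.000301 to 1. That of Sox1 ended without Esrrb replicate 1 (0.122) or 3 (0.0814), or Esrrb+Nanog replicate 2 (0.0504) or 3 (0.119), in a range of 0.00033 to 1.

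Genes of primitive endoderm gave 1 higher and 3 lower of 17, also adjusted over the list alone, and 1 and 6 without Nanog-null replicate 2. The endoderm factor Gata6 fell from 25.2 ± 13 to 6.90 ± 3.5 CPM (log2 change -1.87 ± 0.47, adjusted p = 0.022, range 4.72e-39 to 0.163 over its alternatives), whereas Lama1 rose from 136 ± 41 to 356 ± 42 CPM (adjusted p = 0.00466). The call of Gata6 ended without Esrrb replicate 2 (0.0555) or Esrrb+Nanog replicate 1 (0.0648) or 3 (0.068). The primitive endoderm list was not called (adjusted p = 0.117, range 0.0068 to 0.808), but with 1 library left out it passed without Nanog-null replicate 1 (0.0309) or 2 (0.039) or Esrrb replicate 1 (0.0341). It also passed with the replicate number as a block. Pdgfra fell from 10.4 ± 4.2 to 2.90 ± 1.1 CPM (log2 change -1.85 ± 0.51, adjusted p = 0.0337, range 9.96e-22 to 0.235). This call ended with DESeq2 (0.0803), without Nanog-null replicate 3 (0.0528), Esrrb replicate 2 (0.0506) or 3 (0.106), and without Esrrb+Nanog replicate 1 (0.0966), 2 (0.0637) or 3 (0.0811). Esrrb rose from 803 ± 132 to 1107 ± 48 CPM (log2 change 0.46 ± 0.10, adjusted p = 0.0133, range 3.94e-10 to 1), a call that ended without Esrrb replicate 1 (0.0633) or Esrrb+Nanog replicate 2 (0.0544).

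No other list was called. Among formative genes there were 2 higher and 5 lower of 14, also adjusted over the list alone, 3 and 5 without Nanog-null replicate 2 (adjusted p = 0.125, range 0.0332 to 0.808, and 0.0332 without Esrrb+Nanog replicate 3). Nodal targets gave 1 higher and 3 lower of 8 (1 and 4 adjusted over the list alone, adjusted p = 0.0683, range 0.0138 to 0.613). They passed without Esrrb replicate 1 (0.0341) or 2 (0.037) and without Esrrb+Nanog replicate 2 (0.0466) or 3 (0.0332). LIF and STAT3 targets gave 2 higher of 12 (4 adjusted over the list alone, adjusted p = 0.0914, range 0.000469 to 0.808, and 0.000469 without Esrrb replicate 2). Immediate-early genes gave none of 12 (3 higher and 1 lower adjusted over the list alone, 2 and 1 without Nanog-null replicate 2), with an adjusted p of 0.15, range 0.0385 to 0.808, and 0.0385 without Esrrb replicate 2. FGF and ERK targets gave 1 higher and 4 lower of 16 (2 and 7 adjusted over the list alone, 3 higher without Nanog-null replicate 2, adjusted p = 0.15), with the phosphatase gene Dusp4 down from 121 ± 13 to 39.8 ± 8.3 CPM. BMP targets gave 3 and 2 of 9 (4 and 2 adjusted over the list alone, 0.777), and retinoic acid targets 1 and 2 of 8, also adjusted over the list alone (0.756). Imprinted genes gave 1 higher and 4 lower of 16, also adjusted over the list alone (0.47), with the placental gene Peg10 down from 1950.0 ± 101 to 811 ± 108 CPM.

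Basement membrane genes gave 1 higher and 2 lower of 15 (2 and 2 adjusted over the list alone, 2 and 5 without Nanog-null replicate 2, adjusted p = 0.21), with the collagen gene Col18a1 down from 312 ± 15 to 149 ± 26 CPM. Mitochondrially encoded genes gave 0 higher and 3 lower of 7 (1 and 3 adjusted over the list alone, 0.288), with the oxidase subunit gene mt-Co1 down from 5010.4 ± 725 to 3442 ± 212 CPM. DNA methylation genes gave 0 and 3 of 8 (1 and 3 adjusted over the list alone, 1 higher without Nanog-null replicate 2, 0.278). Germline genes gave 3 and 0 of 12 (3 and 1 adjusted over the list alone, 0.722), with the helicase gene Ddx4 up from 19.9 ± 3.7 to 32.1 ± 3.3 CPM. Trophoblast genes gave 1 and 1 of 14 (2 and 2 adjusted over the list alone, 2 higher without Nanog-null replicate 2, 0.331). Parietal endoderm gave 2 and 0 of 10 (0.437) and visceral endoderm 0 and 1 of 6 (0.683), both also adjusted over the list alone. No member was called, by either adjustment, of the 2-cell-like (11 tested, adjusted p = 0.411), fibroblast (8, 0.357), Wnt (11, 0.829), primitive streak and mesoderm (7, 0.897) and nuclear oxidative phosphorylation lists (15, 0.851). Of the fibroblast genes, 1 was higher without Nanog-null replicate 2. The list median, mean and test differed in sign for germline, primitive streak and imprinted genes.

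**Figure D3:**
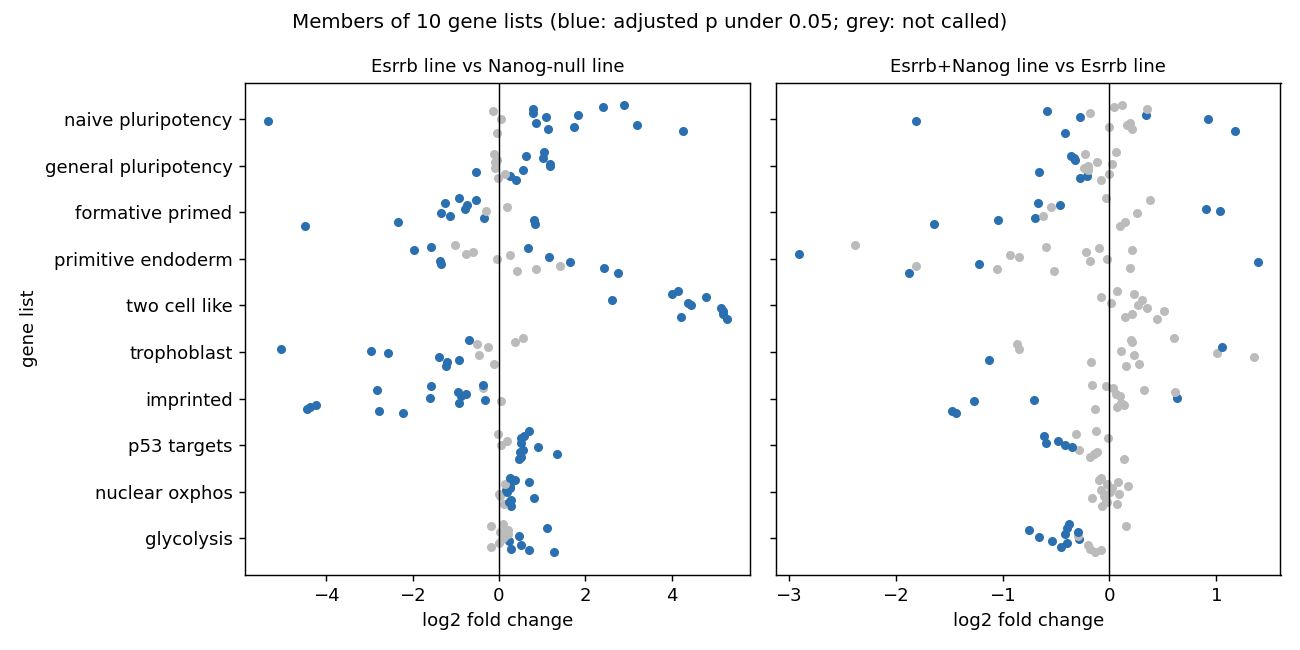
Log2 fold change (x axis) of each tested member of 10 gene lists, for the Esrrb line against the Nanog-null line and for the Esrrb+Nanog line against the Esrrb line; blue points passed an adjusted p of 0.05. The 11 tested 2-cell-like genes were all called in the first panel and none was called in the second.

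Across all genes, 2135 (13.2%) were called in this comparison, 880 higher and 1255 lower, and 234 and 349 of these by more than 2-fold. The share of higher calls was 41.2%, but 59.6% with library totals alone as the scale (1386 higher and 941 lower). The count was 1105 without Esrrb replicate 1 (395 higher and 710 lower), 1378 without Esrrb replicate 3 (542 and 836) and 1215 without Esrrb+Nanog replicate 2 (486 and 729). Besides Duox1, the largest rises included Pvalb, a calcium-binding protein gene, from 0.043 ± 0.048 to 5.51 ± 2.0 CPM, and Mras, a RAS-related GTPase gene, from 9.39 ± 8.5 to 95.5 ± 24 CPM. The log2 change of Pvalb was 6.76, and 7.91 without Esrrb replicate 2, and that of Mras 3.32, and 4.40 without the same library. Adgrg1, an adhesion receptor gene, rose from 1.59 ± 0.28 to 20.5 ± 9.6 CPM. Largest falls included Aass, a lysine degradation gene, from 55.1 ± 16 to 8.90 ± 0.88 CPM, and the chromatin gene Hmga2, from 22.9 ± 5.9 to 4.77 ± 1.2 CPM.

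The comparison of the Esrrb+Nanog line with the Nanog-null line asks how cells with both added genes differ from those with neither. Klf4 rose from 6.65 ± 0.82 to 288 ± 17 CPM (SD, n = 3 per line), a log2 change of 5.43 ± 0.20 (SE, adjusted p = 4.29e-09), and Tfcp2l1, a self-renewal factor downstream of LIF, from 266 ± 27 to 883 ± 49 CPM. Nanog rose by 4.24 ± 0.14 on the log2 scale (adjusted p = 2.58e-09) and Esrrb by 2.00 ± 0.11 (adjusted p = 8.12e-08). Dppa3 fell from 55.3 ± 4.1 to 0.383 ± 0.053 CPM (log2 change -7.15 ± 0.18, adjusted p = 6.64e-10). Lefty1 fell from 151 ± 29 to 4.26 ± 0.14 CPM, and the germ cell repressor Prdm1 from 52.0 ± 3.4 to 6.16 ± 2.2 CPM. Pdgfra was at 2.29 ± 2.0 and 2.90 ± 1.1 CPM and was not called (adjusted p = 0.66). Its Nanog-null libraries were at 0.463, 4.43 and 1.97 CPM, so that mean leans on replicate 2.

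Naive genes were higher in 12 of 15 cases and lower in 3, also adjusted over the list alone (adjusted p = 0.000947, and 0.378 with an estimated correlation, the highest of a range that began at 4.13e-06). Formative genes were lower in 10 of 14 cases and none was higher (1 higher adjusted over the list alone, 9 lower without Nanog-null replicate 2). Dnmt3b fell from 589 ± 46 to 285 ± 10 CPM and Sfrp2 from 56.0 ± 6.7 to 14.8 ± 0.81 CPM. That list had an adjusted p of 0.00285, and 0.696 with an estimated correlation, the highest of a range that began at 7.25e-05. All 11 tested 2-cell-like genes were higher, also adjusted over the list alone (adjusted p = 1.06e-06, and 0.626 with an estimated correlation, the highest of a range that began at 2e-11), with Zscan4a at 17.2 ± 6.8 CPM. Imprinted genes were lower in 14 of 16 cases, also adjusted over the list alone, and in 13 without Nanog-null replicate 2. Their adjusted p was 1.06e-06, and 0.0878 with an estimated correlation, the highest of a range that began at 6.02e-11, with Meg3 at 12.7 ± 2.9 CPM and Rian at 21.2 ± 4.5 CPM. Nuclear oxidative phosphorylation genes were higher in 11 of 15 cases, also adjusted over the list alone, and in 9 without Nanog-null replicate 2. That list had an adjusted p of 0.00783, and 0.822 with an estimated correlation, the highest of a range that began at 0.00224.

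The other 22 lists were not called. General pluripotency gave 7 higher and 6 lower of 15 (adjusted p = 0.544), primitive endoderm 3 and 7 of 17 (0.547, with 4 and 6 without Nanog-null replicate 2), visceral endoderm 1 and 1 of 6 (0.612) and parietal endoderm 4 and 4 of 10 (0.613, with 2 lower without that library). Basement membrane gave 4 and 7 of 15 (0.544), primitive streak 1 and 1 of 7 (0.648), neuroectoderm 2 and 3 of 7 (0.793, with 2 lower without Nanog-null replicate 2) and trophoblast 3 and 7 of 14 (0.325). Germline gave 7 and 2 of 12 (0.156), fibroblast 2 and 4 of 8 (0.544, with 3 lower without that library), FGF and ERK targets 7 and 4 of 16 (0.727) and Wnt targets 5 and 4 of 11 (0.544). LIF and STAT3 targets gave 8 and 3 of 12 (0.156, range 0.0174 to 0.822, and 0.0289 without Esrrb replicate 2). Nodal targets gave 3 and 4 of 8 (0.544), BMP targets 4 and 3 of 9 (0.627, with 2 lower without Nanog-null replicate 2) and p53 targets 7 and 2 of 13 (0.269, with 1 lower without that library). Cell cycle gave 2 and 5 of 16 (0.544, with 1 and 4 without Nanog-null replicate 2), DNA methylation 4 and 4 of 8 (0.99), mitochondrially encoded genes 1 and 3 of 7 (0.544, with none higher without that library), and immediate-early genes 7 and 4 of 12 (0.473, with 2 lower without it). In all of these the counts adjusted over the list alone were the same. Retinoic acid targets gave 1 and 6 of 8 (1 and 7 adjusted over the list alone, 4 lower without Nanog-null replicate 2, adjusted p = 0.156) and glycolysis 3 and 8 of 16 (4 and 8 adjusted over the list alone, 0.547). The list median, mean and test differed in sign for BMP targets and DNA methylation genes.

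Across all genes, 8816 (54.4%) were called, 4405 higher and 4411 lower, and 1301 and 1701 of these by more than 2-fold. Among the largest rises were Inhbb, an activin subunit gene, from 0.400 ± 0.047 to 26.4 ± 16 CPM, and Mras, from 1.53 ± 0.78 to 95.5 ± 24 CPM. The interferon-induced GTPase gene Gbp2, at 8.93 ± 5.6 CPM in the Nanog-null line, had 0 counts in the Esrrb+Nanog line and was at least 239-fold lower. Ddx3y was at least 2010-fold lower, Uty at least 1150-fold lower, and Eif2s3y had 3 counts, a ratio of 2450 (95% counting interval 839 to 11900). The fitted log2 change of Gbp2 was -10.92, and -10.30 without Nanog-null replicate 2, and that of Eif2s3y was -11.10, and -11.99 without Esrrb+Nanog replicate 2. No called list in any of the 3 comparisons kept its call with an estimated correlation. The rotation test fry, which asks whether a list's genes move on balance 1 way without reference to other genes, called 18, 8 and 16 of 27 lists in the order given here.

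Klf4 rose in both steps, while Dnmt3a and Tdh rose in the Esrrb line and fell in the Esrrb+Nanog line. In total 638 genes were called in opposite directions in the first and second comparison, 389 up then down and 249 down then up, where independent lists would give 304 and 213. A further 669 were called in the same direction, 241 up in both and 428 down in both, where independent lists would give 213 and 304. The balance of the opposite calls depended on the scale, with 286 up then down and 386 down then up when library totals alone were used. The opposite count was 350 without Esrrb replicate 1 (240 up then down and 110 down then up) and 411 without Esrrb+Nanog replicate 2 (254 and 157), and 165 were down then up without Esrrb replicate 3. Both comparisons use the Esrrb libraries. In 20 simulations of unchanged groups no gene was called in both, but these groups held almost no calls to share (at most 2 in any comparison), so that 0 sets no level for these counts. Fold changes of the first and second comparison had a correlation of 0.015 across genes, which are not independent replicates, against -0.49 simulated, and a covariance of 0.0072 against -0.0238, a difference of 0.031.

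Genes such as Klf4, Meg3 and Zscan4a differed from the Nanog-null line in the same direction in both other lines, as 6441 genes did, 3190 higher and 3251 lower. Independent lists would share 1067 and 1069, and the simulated 0 sets no level here either. Their fold changes had a correlation of 0.898 across genes against 0.507 simulated, and a covariance of 0.9791 against 0.0249, a difference of 0.954. The simulated groups shared their controls too, so the covariance of 0.0249 is what simulated library noise in shared controls would give. With 3 Nanog-null libraries the controls cannot be divided into parts of at least 2 to check this. Anything particular to the single Nanog-null line would enter both comparisons. So would anything that both other lines share apart from the added Esrrb. Part of the excess may come from either. Of 16198 tested genes, 9471 (58.5%) differed among the 3 lines.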

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

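With the fold change test against 1.5 the called genes fell to 2488 for the Esrrb line against the Nanog-null line, 233 for the Esrrb+Nanog line against the Esrrb line and 3063 for the Esrrb+Nanog line against the Nanog-null line, with 48 opposite and 2019 same-direction calls, because that test asks for a larger change. With 1 library left out, called genes of the Esrrb+Nanog line against the Esrrb line ran from 1105 to 2374 and opposite calls from 350 to 611; the cause was not tested. Without a low-count filter the prior degrees of freedom of edgeR became infinite, against 5.68 with the filter, so each gene's own spread was replaced by the trend, and very small adjusted p-values of that alternative carry little weight. The replicate block gave 7997, 2381 and 8946 called genes and moved the primitive endoderm list of the Esrrb+Nanog line against the Esrrb line to an adjusted p of 0.03. It also added calls for 5 named genes and changed no other call of a named gene or list; of all called genes 7651, 2031 and 8662 were shared with it. Libraries with the same number had correlations of -0.025 to 0.278, over 0.1 in 3 of 9 pairs. Replicate 2 correlated best with its own number in all 3 comparisons (0.107, 0.278 and 0.071), and replicate 3 in none (0.002, -0.025 and -0.018). Replicate 1 did so in both comparisons with the Nanog-null line (0.025 and 0.01). It did not for the Esrrb+Nanog line against the Esrrb line (0.158). Whether the numbers pair the libraries therefore stays open. Of 1962 values of named genes with 1 library left out, 52 lost and 9 gained a call, and of 1718 with other settings 60 lost and 21 gained one. Of 729 list tests with 1 library left out, 6 lost and 20 gained a call, and of 636 with other settings 20 lost and 44 gained one. Of those 44 gains 25 came from fry, which asks another question, and of the 20 losses 17 came from camera with an estimated correlation. No called value changed sign. At this depth 3 counts correspond to 0.0943 to 0.139 CPM, and changes below that were not detectable.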

Other observations

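Only the test of summed X-linked copies in the Esrrb line had its prediction written before its values were seen; the regroupings were planned beforehand but given a prediction after they were run, and every other test in these paragraphs was chosen after results were seen.

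The near absence of reads of 6 Y-linked genes in both Esrrb lines could have come from reads assigned to X-linked copies. The gain of the X-linked copies over the loss of the Y-linked genes was 0.833 (SE 0.485) in the Esrrb line and -0.103 (SE 0.48) in the Esrrb+Nanog line, and neither sum decides, because the copies varied too much between libraries. Single pairs go both ways. In the Esrrb line the ratio was 1.27 (SE 0.442) for Ddx3y and Ddx3x, 3.33 (SE 1.03) for Uba1y and Uba1 and 0.22 (SE 0.209) for Uty and Kdm6a. In the Esrrb+Nanog line it was 0.651 (SE 0.554), -2.07 (SE 1.97) and -0.00246 (SE 0.165). Such a ratio takes the X-linked copy's own expression as unchanged. The median log2 change of X-linked genes in the Esrrb+Nanog line against the Nanog-null line was -0.189, outside the autosome range of -0.059 to 0.079. The ratio for Uty in that line therefore excludes reassignment only if Kdm6a's own expression did not change. The ratios do not decide for Ddx3y, Uba1y, Zfy1 and Usp9y. In the same count table Ddx3y, Uty, Uba1y, Zfy1 and Usp9y had 5787, 3311, 479, 263 and 143 reads in the Nanog-null line. If all columns were counted alike, reads told apart in that line would be told apart in the others. This argues against reassignment for these genes. For Eif2s3y and Eif2s3x the ratios were 0.0643 (SE 0.027) and -0.0238 (SE 0.0363). Eif2s3x was at 71.4 CPM in the Esrrb line and 63.3 CPM in the Esrrb+Nanog line, less than the 91.8 CPM that Eif2s3y lost. This excludes reassignment of all Eif2s3y reads to Eif2s3x in both lines. By summed Y-linked level 0 libraries were out of place, which restates the pattern and adds no support of its own. The pattern itself argues against a library exchanged with the Nanog-null line but cannot tell the Esrrb lines apart. Loss or silencing of the male-specific Y stays open: 0 of 6 tested genes outside the part shared with X kept over 10% of their level, but this restates the pattern, and the boundary was set after Gm47283 was seen to keep 93.2%.

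The fall of imprinted genes could reflect differentiated cells in the Nanog-null libraries. The median log2 ratio of Nanog-null replicate 2 to its partners was 0.093 over the 14 called imprinted genes. It was 2.187 over the 5 fibroblast genes called lower and 0.911 over all 8 tested. Standard errors of the mean over genes were 0.08 for the 14 and 0.338 for the 5, and treat genes as independent. All 14 imprinted genes stayed called without that library. This speaks only of what sets replicate 2 apart, and differentiated cells common to all 3 Nanog-null libraries stay open. A change of the Dlk1-Dio3 cluster alone is excluded by a median log2 change of -0.902 in the tested imprinted genes outside the cluster, where 10 of 12 were lower. The rise of the Zscan4 genes in the Esrrb line was not reads moved between Zscan4 copies, since their summed level rose by 4.997 on the log2 scale (SE 0.39). Nor was it a burst in 1 library, since the lowest Esrrb library was 16.2 times the highest Nanog-null library in that sum. The other 2-cell-like genes, among them the Usp17l genes, were not tested in these ways.

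Regrouping the libraries gave at most 0 calls for the Esrrb line against the Nanog-null line (real 7849), 78 for the Esrrb+Nanog line against the Esrrb line (real 2135) and 0 for the Esrrb+Nanog line against the Nanog-null line (real 8816), so in each only 1 of 10 splits, the real one, was as large. These splits are too few for a share under 0.05. For any difference among the 3 lines, 1 of 100 regroupings, the real one, reached 9471 calls and the highest other had 6759. This argues against a chance split of these libraries. Each group is a single line, so it shows only that libraries of 1 line resemble each other. Whether primitive endoderm cells passed the sorting gate was not tested.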
